A study of Homo sapiens with 36 samples.

How the data were processed

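RNA levels were measured on 36 Affymetrix expression arrays with 22277 probe sets, each a group of short DNA probes that together read the transcripts of a gene. The samples came from 2 established human cancer cell lines: NCI-H1299, from a non-small cell lung cancer, and MiaPaCa-2, from a pancreatic adenocarcinoma. Per the labels, the cells received the solvent DMSO, 0.5 µM MS417 or 10 µM C1 for 3 h or 6 h. MS417 is an inhibitor of the BET proteins, which bind acetylated histones through bromodomains, and C1 is the compound that the labels call inactive. The 2 compounds were given at different doses. Each of the 12 combinations of line, treatment and time had 3 arrays, described as biological triplicates. Biotin-labelled cRNA was made from total RNA and hybridised, per the labels.

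The deposited values are probe set intensity on a linear scale. How the authors summarised the probes, subtracted background or scaled the arrays is given in no source used here. In every array between 15.6% and 17.5% of the probe sets had a value below 0, so background had been subtracted. The mean intensity ran from 268 to 572 between arrays, so the deposited intensity had not been brought to a common level. The number of arrays limits the precision: the median standard error (SE) of a log2 difference was 0.0876 between groups and 0.124 for a difference of differences. The median half-width of the 95% confidence intervals was 0.18 and 0.255.

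Intensities were quantile normalised over the 36 arrays, values under a floor of 32 were set to 32, and log2 was taken. Quantile normalisation gives all arrays the same distribution, so a change in total RNA per cell cannot be seen. The first plan had taken the deposited values without scaling. Because they turned out not to be scaled, quantile normalisation was put in their place before any test was run, and the unscaled values became an alternative. The annotation listed 20113 probe sets, of which 19070 named 1 symbol. Per gene the probe set with the highest mean over all arrays was kept. Of 11963 genes, the 8639 above the floor on at least 1 array were tested. Symbols are current ones, so HIST2H2BE appears as H2BC21. No genome build belongs to the array table, so no positions are given.

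One limma fit (limma 3.58.1, R 4.3.3) held the means of the 12 groups, with 24 residual degrees of freedom and 1.96 prior degrees of freedom. Contrasts compared MS417 with DMSO, C1 with DMSO and MS417 with C1 in each line at each time. Further contrasts compared the MS417 change between lines and between times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose", "fell" and "changed" refer to called genes. The tests are 2-sided. Sets of genes were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 22 lists of a comparison. The lists cover P-TEFb and BET regulators, replication-type histones, MYC and ribosome biogenesis, immediate early genes, NF-kB targets, interferon response, G1/S, G2/M, CDK inhibitors and p53 targets, apoptosis, cholesterol, ATF4 and the unfolded protein response, NRF2, heat shock, TGF-beta and YAP, autophagy and lysosome, aryl hydrocarbon receptor targets, hypoxia and glycolysis, markers of fibroblasts, leukocytes and epithelium, and reference genes.

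The comparisons, lists, thresholds, other settings and the rule for named genes were set before the data were examined. The rule names HEXIM1, MYC, BRD2, BRD3, CDK9, SERPINI1, H2BC21, FOSL1, CCND1 and CDKN1A in every comparison. It adds, per MS417 comparison with DMSO, the 10 highest rises and the 10 largest falls among called genes whose 3 treated arrays all lay outside the range of the 3 DMSO arrays, which chance alone gives for 10% of genes. For C1 it adds 5 and 5, for each difference of differences 5 and 5, and 10 and 10 of the genes called the same way in all 4 MS417 comparisons. From each list it adds up to 4 called members with the largest change. A group with all 3 arrays at the floor gives only a bound, written "at least".

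The steps were tested on simulated data. The changed genes were drawn from those with a DMSO mean over log2 6, so recovery for genes nearer the floor was not tested. Changes of 1 and 2 on the log2 scale, put into 50 genes each, were recovered for 100% of the genes in each MS417 comparison. A change of 0.5 was recovered for 78% to 82% and a change of 0.3 for 48% to 54%. Between 5.14% and 8.24% of the calls on simulated data were false, above the nominal 5%. Within groups, arrays correlated at 0.991 to 0.995.

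The other settings tried were unscaled values, median scaling, a floor of 16, leaving out the 40% dimmest genes, all probe sets or their mean per gene, a trended robust prior, the arrays of 1 cell line or of the compared groups alone, the replicate number as a block, a change of at least 2-fold, leaving out each array, and a correlation estimated per list for camera. Scaling by the 75th percentile, a filter for genes above the floor in a whole group and the DMSO arrays of 3 h as control were added after the data had been seen. Probe sets with several symbols or none were left out of the comparisons because they name no single gene.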

Results

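Expression was measured in NCI-H1299 lung cancer cells and MiaPaCa-2 pancreatic cancer cells after 3 h or 6 h with DMSO, 0.5 µM MS417 or 10 µM C1, with 3 arrays in each of 12 groups. The arrays give intensities and no read counts, and their number sets the precision. The 3'/5' signal ratio, a measure of RNA integrity, was 0.969 to 1.22 for ACTB and 0.915 to 1.04 for GAPDH over the 36 arrays. The series title asks which genes a BET inhibitor modulates in cancer cells and may serve as a pharmacodynamic marker. Values below are log2 changes with their SE and n = 3 arrays per group, unless a fold is named. The SE of a gene rests on its spread pooled over all 12 groups of both lines, not on the compared groups alone. A group with all arrays at the floor adds no spread. For genes with such groups the SE and the adjusted p can therefore be too small.

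The comparison of MS417 with DMSO at 3 h in NCI-H1299 asks for the earliest changes in the lung line. Histone genes rose together, and genes of ribosome biogenesis and of mitosis fell. H2AC6, a histone H2A gene, was 6.55-fold higher (2.71 ± 0.047). HEXIM1, whose product holds the transcription kinase P-TEFb inactive, was 3.53-fold higher (1.82 ± 0.133, its other probe set 2.86), and CDKN1A, which encodes the cell cycle inhibitor p21, was 3.14-fold higher (1.65 ± 0.117). DKK1, a secreted inhibitor of Wnt signalling, was 5.44-fold lower (−2.44 ± 0.071), with 2 of the 3 treated arrays at the floor. Of 8639 genes, limma called 2268 at an adjusted p under 0.05, 1045 higher and 1223 lower, and 128 of them changed by at least 2-fold (309 called without scaling, 145 higher and 164 lower, and 1403 higher and 1082 lower with 75th percentile scaling). In the list of replication-type histones 19 of 27 genes rose and 0 fell, with a median of 0.55 (camera adjusted p = 2.5e-15), among them H2BC21 (2.21 ± 0.138), H2BC5 (2.06 ± 0.105) and H3C8 (at least 3.12-fold higher). In the MYC and ribosome biogenesis list 16 of 43 genes fell and 0 rose, with RRS1 at −1.69 ± 0.219 and PPRC1 at −1.02 ± 0.127 (camera adjusted p = 0.000898), and the list median of −0.08 was 0.05 without scaling. In the G2/M list 16 of 39 genes fell and 0 rose, with KIF14 at −0.62 ± 0.07 and AURKA, a mitotic kinase, at −0.49 ± 0.044 (camera adjusted p = 4.06e-05), and the median of −0.12 was 0.02 without scaling. The unscaled median of all genes in this comparison was 0.09, above the unscaled medians of both lists. Of 21 CDK inhibitors and p53 targets 8 rose and 1 fell (camera adjusted p = 0.00079), with GADD45B at 1.18 ± 0.2 and SESN1 at 0.89 ± 0.104. Of 34 immediate early genes 16 rose, led by EGR1 (2.02 ± 0.074) and ID2 (1.96 ± 0.13), and 11 fell (camera adjusted p = 0.0385). That call is lost with an estimated correlation (adjusted p = 0.105 with an estimated correlation) and with 75th percentile scaling (median 0.09 against 0.18).

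Smaller groups also rose at 3 h in NCI-H1299. Of 21 cholesterol genes 6 rose and 1 fell (camera adjusted p = 0.0227), with INSIG1, which restrains sterol synthesis, at 1.26 ± 0.098. In the ATF4 and unfolded protein response list 12 of 30 genes rose and 3 fell (camera adjusted p = 0.0127), with ATF3 at 0.99 ± 0.081 and XBP1 at −0.61 ± 0.136. Of 27 hypoxia and glycolysis genes 6 rose and 0 fell (camera adjusted p = 0.0385), with the glucose transporter gene SLC2A3 at 0.63 ± 0.093. Adjusted over the list alone, the counts at 3 h in NCI-H1299 were the same except for immediate early genes (17 higher, 11 lower), ATF4 and the unfolded protein response (15 and 4) and G1/S (6 and 9, against 5 and 7). Among the genes named in advance, SERPINI1, the neuroserpin gene, rose by 1.23 ± 0.078 and BRD2, itself a BET gene, by 0.82 ± 0.068. MYC fell by 0.47 ± 0.051 and FOSL1, an AP-1 transcription factor gene, fell by 1.30 ± 0.089. CDK9, the P-TEFb kinase gene, rose by 0.40 ± 0.136 (limma adjusted p = 0.0294), a call that ended without MS417 replicate 1 (0.38) or 2 (0.29) and without DMSO replicate 1 (0.27) or 2 (0.40). BRD3 stood at 0.17 ± 0.083 (limma adjusted p = 0.148) and CCND1, the cyclin D1 gene, at 0.03 ± 0.138 (limma adjusted p = 0.997). The other named rises were H2AJ (2.06), ZCCHC24 (1.85), the ephrin ligand gene EFNB2 (1.72) and KRCC1 (1.68). The other named falls were ZFP64 (−1.88), COA7 (−1.87), TMEM143 (−1.87), AEN (−1.85) and ZNF586 (−1.64), with SEMA4C at least 4.15-fold, KIAA0753 at least 3.15-fold and ZNF112 at least 3.14-fold lower.

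At 6 h in NCI-H1299 the same question is asked of the later response. H2AC6 was 9.97-fold higher (3.32 ± 0.047), H2BC5 was 7.99-fold higher (3.00 ± 0.105), and HEXIM1 was 3.56-fold higher (1.83 ± 0.133, its other probe set 2.87). The largest falls were in DCLRE1A, a DNA repair nuclease gene, 7.82-fold lower (−2.97 ± 0.128), DKK1 (−2.60 ± 0.071), G0S2 (−2.58 ± 0.091) and ZMYND8, a chromatin reader gene, 5.96-fold lower (−2.58 ± 0.08, with other probe sets at −2.12, 0 and 0). limma called 3339 genes, 1526 higher and 1813 lower, of which 267 changed by at least 2-fold (3988 called without scaling, 95 higher and 3893 lower, and 1804 higher and 1598 lower with 75th percentile scaling). Of 27 histone genes 21 rose and 0 fell, with a median of 1.09 (camera adjusted p = 6.03e-19), and H2AC14 was at least 5.76-fold higher. In the MYC and ribosome biogenesis list 22 of 43 genes fell and 1 rose (camera adjusted p = 9.53e-05), with BRIX1 at −0.89 ± 0.087 and POLR1D at −0.82 ± 0.076. In the G2/M list 21 of 39 fell and 3 rose (camera adjusted p = 2.85e-05), with KIF14 at −1.09 ± 0.07 and BUB1B, a spindle checkpoint gene, at −0.78 ± 0.061. Of 21 CDK inhibitors and p53 targets 10 rose and 1 fell (camera adjusted p = 9.53e-05), with CDKN1A at 1.86 ± 0.117 and SESN1 at 1.52 ± 0.104. Of 23 NRF2 genes 10 rose and 2 fell (camera adjusted p = 0.0345), with GCLC, a glutathione synthesis gene, at 1.02 ± 0.065 and SLC7A11 at −1.25 ± 0.14. Of 28 autophagy and lysosome genes 10 rose and 1 fell (camera adjusted p = 0.023), with ULK1 at 1.06 ± 0.21 and MAP1LC3B at 0.62 ± 0.044. In the NF-kB list 8 of 21 genes fell and 0 rose, with NFKBIA at −0.86 ± 0.066 and CXCL2 at least 2.43-fold lower (camera adjusted p = 0.0352), a call that is lost with an estimated correlation (adjusted p = 0.113 with an estimated correlation). Without scaling, the median of all genes shifted by −0.45 in this comparison. Relative to 0, the unscaled medians of the p53, NRF2 and autophagy lists were −0.32, −0.35 and −0.42, and those of the histone list 0.92.

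Adjusted over the list alone, the 6 h counts in NCI-H1299 were the same except for histones (22 higher), G2/M (22 lower) and immediate early genes (13 higher and 8 lower, against 12 and 8). SERPINI1 rose by 1.71 ± 0.078, BRD2 by 1.25 ± 0.068, H2BC21 by 2.75 ± 0.138, CDK9 by 0.70 ± 0.136 and BRD3 by 0.34 ± 0.083 (−0.18 without scaling). FOSL1 fell by 1.52 ± 0.089 and MYC fell by 0.42 ± 0.051. CCND1 stood at −0.28 ± 0.138 (limma adjusted p = 0.121). The other named rises were H2BC6 (2.37), H2BC12L (2.10), ID2 (2.09) and H2BC9 (2.08), with ZCCHC24 at least 5.49-fold and DHRS2 at least 4.83-fold higher. The other named falls were NAV3 (−2.29), the deacetylase gene HDAC9 (−2.27), TMEM143 (−2.07), the pentraxin gene PTX3 (−2.03) and PIGC (3.99-fold lower), with ZFP64 at least 4.14-fold lower.

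In MiaPaCa-2 the comparison of MS417 with DMSO at 3 h asks the same of the pancreatic line. The lists of histones, immediate early genes, and CDK inhibitors and p53 targets rose, and those of ribosome biogenesis and G2/M fell. H2AJ, an H2A variant gene, was 9.20-fold higher (3.20 ± 0.119), IER5 was 5.89-fold higher (2.56 ± 0.054) and BTG1, an antiproliferative gene, was 5.36-fold higher (2.42 ± 0.107). FJX1 was 6.09-fold lower (−2.61 ± 0.107, with 2 of 3 treated arrays at the floor) and GAS1 was 5.54-fold lower (−2.47 ± 0.068). The other probe set of GAS1 read −0.37. limma called 3214 genes, 1462 higher and 1752 lower, of which 371 changed by at least 2-fold (885 called without scaling, 465 higher and 420 lower, 1983 and 1359 with median scaling and 1894 and 1533 with 75th percentile scaling). Of 27 histone genes 11 rose and 0 fell (median 0.13, camera adjusted p = 3.49e-05), with H2AC6 at 2.63 ± 0.047 and H2BC5 at 2.05 ± 0.105. In the MYC and ribosome biogenesis list 25 of 43 genes fell and 2 rose (median −0.24, camera adjusted p = 3.49e-05), with BYSL at −1.76 ± 0.1 and PPRC1 at −1.63 ± 0.127. In the G2/M list 21 of 39 fell and 3 rose (camera adjusted p = 5.42e-05), with AURKA at −1.21 ± 0.044 and NDC80 at −1.07 ± 0.043. Of 34 immediate early genes 19 rose and 8 fell (camera adjusted p = 9.49e-05), with FOS at least 3.87-fold higher and ZFP36 at 1.46 ± 0.093. Of 21 CDK inhibitors and p53 targets 10 rose and 3 fell (camera adjusted p = 0.00281), with GADD45B at 2.11 ± 0.2, GADD45A at 1.88 ± 0.089 and the death receptor gene FAS at −0.77 ± 0.119. In the ATF4 and unfolded protein response list 14 of 30 rose and 3 fell (camera adjusted p = 0.00281): HERPUD1 stood at 1.08 ± 0.082 and DNAJB9 at 0.90 ± 0.06, while TRIB3, an ATF4 target, stood at −1.13 ± 0.084. Of 18 heat shock genes 8 rose and 1 fell (camera adjusted p = 0.00882), with DNAJB4 at 1.42 ± 0.122. Of 27 hypoxia and glycolysis genes 10 rose and 1 fell (camera adjusted p = 0.00134), with KDM3A at 0.91 ± 0.044 and DDIT4 at −0.75 ± 0.139. In the NF-kB list 9 of 21 fell and 2 rose, with LIF at −1.91 ± 0.154, CXCL8 at −1.13 ± 0.042 and NFKBIE at least 3.03-fold higher (camera adjusted p = 0.0164), a call that is lost with an estimated correlation (adjusted p = 0.0842 with an estimated correlation). The NF-kB median was 0 and the mean −0.33.

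Adjusted over the list alone, the 3 h counts in MiaPaCa-2 differed for ribosome biogenesis (27 lower), G2/M (4 higher, 24 lower), immediate early genes (20 and 9), CDK inhibitors and p53 targets (13 higher), ATF4 and the unfolded protein response (15 higher), heat shock (9 and 2), autophagy (8 higher, against 7), G1/S (17 lower, against 16) and interferon response (3 lower, against 4). BRD2 rose by 1.52 ± 0.068, H2BC21 by 2.00 ± 0.138 and CDKN1A by 1.74 ± 0.117, and SERPINI1, at the floor on all DMSO arrays, was at least 3.80-fold higher. MYC fell by 0.44 ± 0.051, and FOSL1 fell by 0.48 ± 0.089. CCND1 fell by 0.39 ± 0.138 (limma adjusted p = 0.0259), a call that ended with median scaling (−0.31) and without MS417 replicate 1 (−0.38) or 3 (−0.34) or DMSO replicate 2 (−0.36). HEXIM1 rose by 0.40 ± 0.133 (limma adjusted p = 0.0169) on its brighter probe set, a call that ended without MS417 replicate 1 (0.36) or 2 (0.34), while its other probe set read 1.76. CDK9 stood at 0.12 ± 0.136 (limma adjusted p = 0.584) and BRD3 at 0.05 ± 0.083 (limma adjusted p = 0.768). The other named rises were CHCHD7 (2.58), TUFT1 (2.49) and the growth factor gene HBEGF (2.48), with RGS2 at least 8.41-fold, EFNB2 at least 7.85-fold and TRIM36 at least 6.43-fold higher. The other named falls were BHLHE41 (−2.23), the Cajal body gene COIL (−2.17), HOXB2 (−2.07), ABT1 (−2.06), WT1 (−2.02) and SCAF8 (−1.95), with RUNX1-IT1 at least 3.97-fold lower and COA7 lower by at least 2.20 on the log2 scale.

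At 6 h in MiaPaCa-2 more genes were called than in the other MS417 comparisons, but without scaling fewer than at 6 h in NCI-H1299. CNNM4 was 12.5-fold higher (3.64 ± 0.152), H2AC6 was 8.01-fold higher (3.00 ± 0.047), and EFNB2 was at least 9.12-fold higher. ZMYND8 was 13.1-fold lower (−3.71 ± 0.08, with other probe sets at −3.59, −0.24 and −0.22), HDAC9 was 10.8-fold lower (−3.43 ± 0.115), TNFSF4, the OX40 ligand gene, was 10.8-fold lower (−3.43 ± 0.104) and PDE10A, a phosphodiesterase gene, was at least 11.3-fold lower. MYC, lower at 3 h, was 1.23-fold higher at 6 h (0.30 ± 0.051). limma called 4430 genes, 2064 higher and 2366 lower, of which 700 changed by at least 2-fold (1781 called without scaling, 813 higher and 968 lower, 2984 and 1615 with median scaling and 2336 and 2178 with 75th percentile scaling). Of 27 histone genes 12 rose and 0 fell (median 0.34, camera adjusted p = 2.59e-05), with H2BC5 at 2.49 ± 0.105, H2BC21 at 2.36 ± 0.138 and H2BC6 at 2.33 ± 0.093. Of 34 immediate early genes 24 rose and 2 fell (median 0.48, camera adjusted p = 3.64e-08), with JUNB at 2.08 ± 0.146 and KLF2 at 1.54 ± 0.099. In the G2/M list 25 of 39 fell and 5 rose (camera adjusted p = 5.11e-05), with AURKA at −1.63 ± 0.044 and BUB1B at −1.43 ± 0.061. In the MYC and ribosome biogenesis list 25 of 43 fell and 8 rose (camera adjusted p = 0.00543), with GAR1 at −1.74 ± 0.162 and BYSL at −1.64 ± 0.1, a call that ended with median scaling (median −0.02 against −0.27). Of 21 CDK inhibitors and p53 targets 14 rose and 4 fell (camera adjusted p = 0.0031), with GADD45B at 2.22 ± 0.2 and CDKN1A at 2.00 ± 0.117. In the ATF4 and unfolded protein response list 14 of 30 rose and 3 fell (camera adjusted p = 0.0303): DNAJB9 stood at 1.19 ± 0.06 and ASNS at 0.85 ± 0.065, while TRIB3 stood at −1.61 ± 0.084 and DDIT4 at −1.19 ± 0.139. Of 28 autophagy and lysosome genes 13 rose and 2 fell (camera adjusted p = 0.0317), with WIPI1 at 1.11 ± 0.089. Of 27 hypoxia and glycolysis genes 12 rose and 1 fell (camera adjusted p = 0.00883), with NDRG1 at 1.13 ± 0.19.

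Adjusted over the list alone, the 6 h counts in MiaPaCa-2 differed for immediate early genes (25 higher), G2/M (6 higher, 26 lower), apoptosis (7 higher, against 6), TGF-beta and YAP (7 higher, against 8) and leukocyte markers (0 lower, against 1). BRD2 rose by 1.61 ± 0.068, CDK9 by 0.72 ± 0.136 and BRD3 by 0.32 ± 0.083, which was 0.20 without DMSO replicate 2, and SERPINI1 was at least 6.93-fold higher. CCND1 fell by 0.81 ± 0.138 against DMSO and read −0.45 against C1 (its other probe set −0.56 and −0.65). HEXIM1 rose by 0.39 ± 0.133 (limma adjusted p = 0.014) on its brighter probe set, a call that ended without MS417 replicate 1 (0.30), while its other probe set read 1.55. FOSL1 stood at 0.02 ± 0.089 (limma adjusted p = 0.939). The other named rises were CEMIP2 (3.05), CSRP2 (2.92), CHCHD7 (2.87) and TUFT1 (2.58), with TRIM36 at least 6.18-fold and the YAP target gene CCN2 at least 5.95-fold higher. The other named falls were KEAP1, whose product marks NRF2 for degradation (−3.09, with 2 of 3 treated arrays at the floor), RIN2 (−3.01), FJX1 (−2.62), JADE2 (−2.56) and HOXC6 (−2.51), with KIAA0753 at least 6.42-fold lower.

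**Figure D1:**
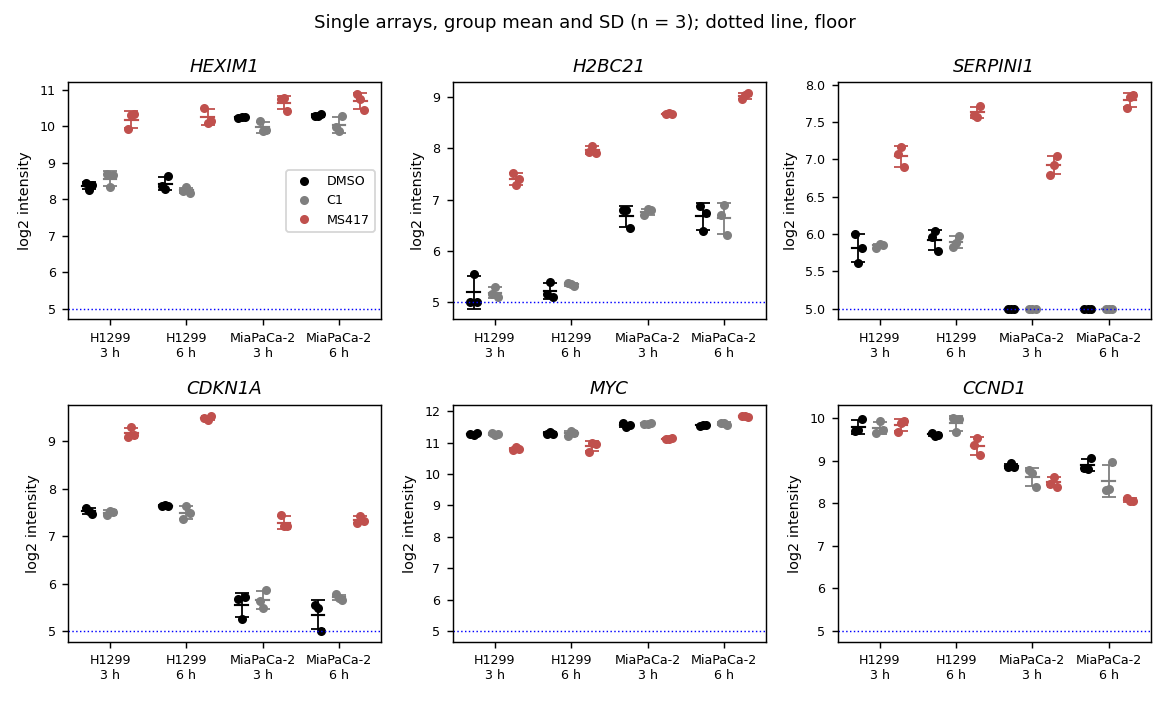
Log2 intensity (y axis) of 6 genes named in advance on single arrays, by cell line and time (x axis), with points for arrays, a bar for the mean and whiskers for the SD (n = 3); the dotted line is the floor. MS417 arrays of HEXIM1, H2BC21, SERPINI1 and CDKN1A lie above the DMSO and C1 arrays of the same line and time, whereas MYC in MiaPaCa-2 lies below them at 3 h and above them at 6 h.

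Other lists were not called by camera in an MS417 comparison with DMSO, or only in those given above. Counts follow the order 3 h and 6 h in NCI-H1299, then 3 h and 6 h in MiaPaCa-2. Of 27 P-TEFb and BET regulators 7, 12, 8 and 12 rose and 3, 5, 4 and 4 fell (camera adjusted p = 0.363, 0.0642, 0.372 and 0.139), with ZMYND8 among the falls and BRD2 among the rises each time. Of 38 G1/S genes 5, 8, 10 and 11 rose and 7, 13, 16 and 18 fell (camera adjusted p = 0.468, 0.383, 0.834 and 0.602), with CCNE2 at 1.21 ± 0.065 and RFC4 at −1.25 ± 0.066 at 6 h in MiaPaCa-2. Of 22 apoptosis genes 3, 4, 5 and 6 rose and 6, 9, 6 and 10 fell (camera adjusted p = 0.62, 0.383, 0.934 and 0.948), with the BH3-only gene PMAIP1 at 2.21 ± 0.134 at 3 h in MiaPaCa-2 and CFLAR, a caspase-8 inhibitor gene, at −1.49 ± 0.074 at 6 h. In MiaPaCa-2 the apoptosis list had medians of −0.14 and −0.13 but means of 0.05 and 0.01. Of 22 interferon response genes 4, 3, 0 and 3 rose and 3, 3, 4 and 2 fell (camera adjusted p = 0.59, 0.862, 0.762 and 0.845), with a median of −0.003 and a mean of 0.006 at 6 h in NCI-H1299 and IRF7 at 1.66 ± 0.063 at 6 h in NCI-H1299. Of 31 TGF-beta and YAP genes 4, 4, 6 and 8 rose and 5, 9, 4 and 5 fell (camera adjusted p = 0.59, 0.383, 0.819 and 0.446), with the urokinase gene PLAU at −1.58 ± 0.082 at 6 h in NCI-H1299 and CCN1 at 1.79 ± 0.122 at 6 h in MiaPaCa-2. Of 8 aryl hydrocarbon receptor targets 3, 3, 2 and 4 rose and 2, 1, 2 and 0 fell (camera adjusted p = 0.747, 0.178, 0.762 and 0.0686), with TIPARP at 1.94 ± 0.107 at 6 h in MiaPaCa-2. Fibroblast markers (10 genes) had 2, 1, 3 and 2 higher and 0, 0, 0 and 1 lower (camera adjusted p = 0.225, 0.285, 0.253 and 0.675), the last with a median of −0.00 and a mean of 0.09. Leukocyte markers (8 genes) had 0, 1, 1 and 1 higher and 1, 0, 0 and 1 lower (camera adjusted p = 0.862, 0.679, 0.762 and 0.569). Epithelial markers (12 genes) had 1, 0, 4 and 4 higher and 2, 3, 3 and 2 lower (camera adjusted p = 0.949, 0.383, 0.762 and 0.768), the first with a mean of 0.001 and a test pointing down. Reference genes (14) had 3, 4, 3 and 5 higher and 1, 0, 1 and 2 lower (camera adjusted p = 0.462, 0.178, 0.222 and 0.446), with SDHA higher in all 4 comparisons.

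The lists called in some comparisons only gave the following in the others. At 6 h in NCI-H1299 immediate early genes had 12 higher and 8 lower (camera adjusted p = 0.178, median 0 and mean 0.11), ATF4 and the unfolded protein response 12 and 2 (adjusted p = 0.0594), hypoxia 8 and 2 (adjusted p = 0.0642), cholesterol 4 and 2 (adjusted p = 0.178) and heat shock 4 and 1 (adjusted p = 0.178), by camera. At 3 h in NCI-H1299 the NF-kB list had 1 higher and 4 lower (camera adjusted p = 0.357), NRF2 5 and 1 (adjusted p = 0.117), heat shock 5 and 0 (adjusted p = 0.0761) and autophagy 5 and 0 (adjusted p = 0.195). For MiaPaCa-2 at 3 h camera gave cholesterol 5 higher and 0 lower (adjusted p = 0.0627), NRF2 5 and 1 (adjusted p = 0.149) and autophagy 7 and 3 (adjusted p = 0.149). For MiaPaCa-2 at 6 h camera gave NF-kB 3 higher and 7 lower (adjusted p = 0.482), cholesterol 6 and 3 (adjusted p = 0.497, median −0.00267 and mean 0.12), NRF2 7 and 4 (adjusted p = 0.446) and heat shock 8 and 2 (adjusted p = 0.0769). Of 88 tests of lists under MS417, 32 were called at the preset correlation and 29 with an estimated one. The difference is the immediate early call at 3 h in NCI-H1299 and both NF-kB calls. Some kept calls weakened: with the estimated correlation camera gave G2/M an adjusted p of 0.0168, 0.0148, 0.0123 and 0.015. For histones the camera adjusted p was then 1.6e-06, 2.36e-07, 0.00285 and 0.00247. In the differences between lines and between times camera called no list other than the histone, immediate early and ribosome biogenesis lists given below.

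**Figure D2:**
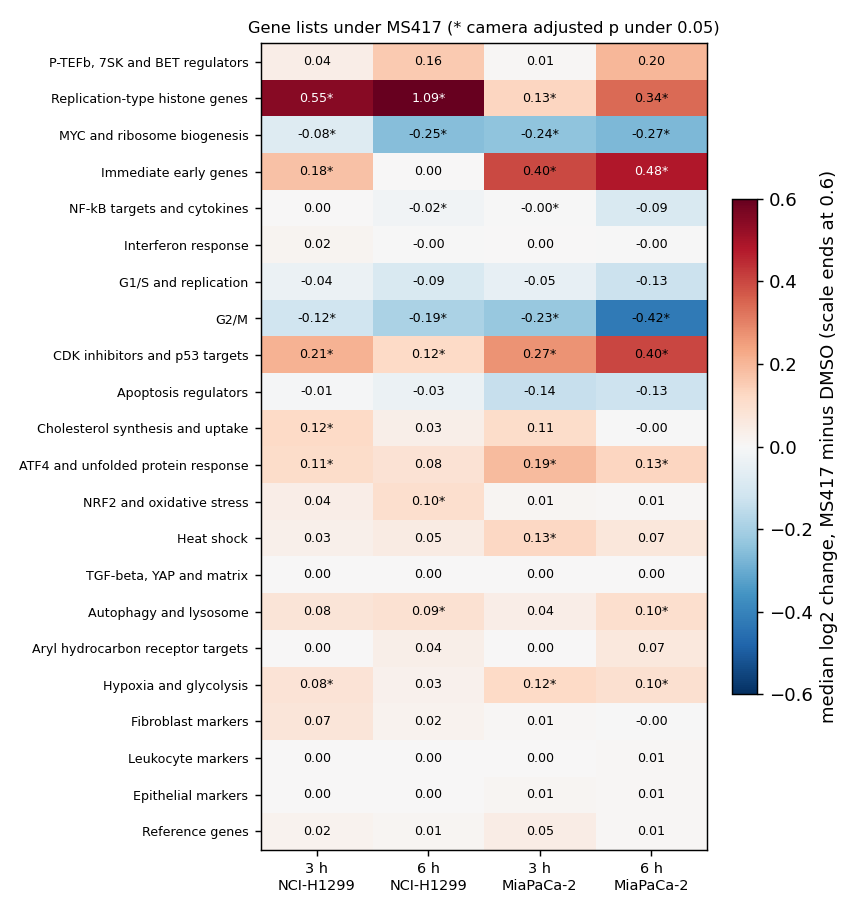
Median log2 change, MS417 minus DMSO, of 22 gene lists (rows of cells) in the 4 comparisons (columns), coloured by value with the scale ending at 0.6; a star marks a camera adjusted p under 0.05. Histone lists read 0.55, 1.09, 0.13 and 0.34, and G2/M lists read −0.12, −0.19, −0.23 and −0.42 (0.02 at 3 h in NCI-H1299 without scaling, against 0.09 for all genes).

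Which genes respond in both lines and at both times bears on the search for a marker. In all 4 MS417 comparisons 448 genes rose and 559 fell, against 7.46 and 14.3 for independent lists of these sizes. The 10 rises with the largest smallest change were H2AC6, H2BC5, H2BC21, H2AJ, CDKN1A, H2BC6, ZCCHC24, EFNB2, H2BC9 and CEMIP2, so 6 of the 10 are histone genes, all read by probe sets marked as shared with other transcripts. H2AC6 rose by at least 2.63 in each comparison, and CDKN1A by at least 1.65. The 10 falls were COA7, ZFP64, KIAA0753, HOXB2, BNIP1, ZMYND8, MTPAP, ZNF112, ZNF764 and RCHY1. HEXIM1, SERPINI1, BRD2, H2BC21 and CDKN1A, named in advance, are among the rises, and HEXIM1 is the one with calls that end when single arrays are left out. Of the 1007 genes, 28 rose and 16 fell by at least 2-fold in all 4, and 984 were called in no C1 comparison with DMSO. C1 called only 2, 2, 6 and 202 of all 8639 genes, so nearly all tested genes lack a C1 call. The count of 984 therefore says little about these genes in particular. Without scaling 122 genes were called the same way in all 4. Another 51 genes were called in all 4 with mixed directions, MYC among them. For SEMA4C, ZMYND8, JADE2, BNIP1, RCHY1, AURKA, GADD45B and CFLAR another probe set was not called in at least 1 comparison where the gene was. Other probe sets of EGR1, ZCCHC24, DHRS2, EFNB2, WT1, CSRP2, PDE10A, ZNF764, SLC7A11 and DNAJB9 gave a change smaller by over 1.5 times in at least 1 comparison named above.

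**Figure D3:**
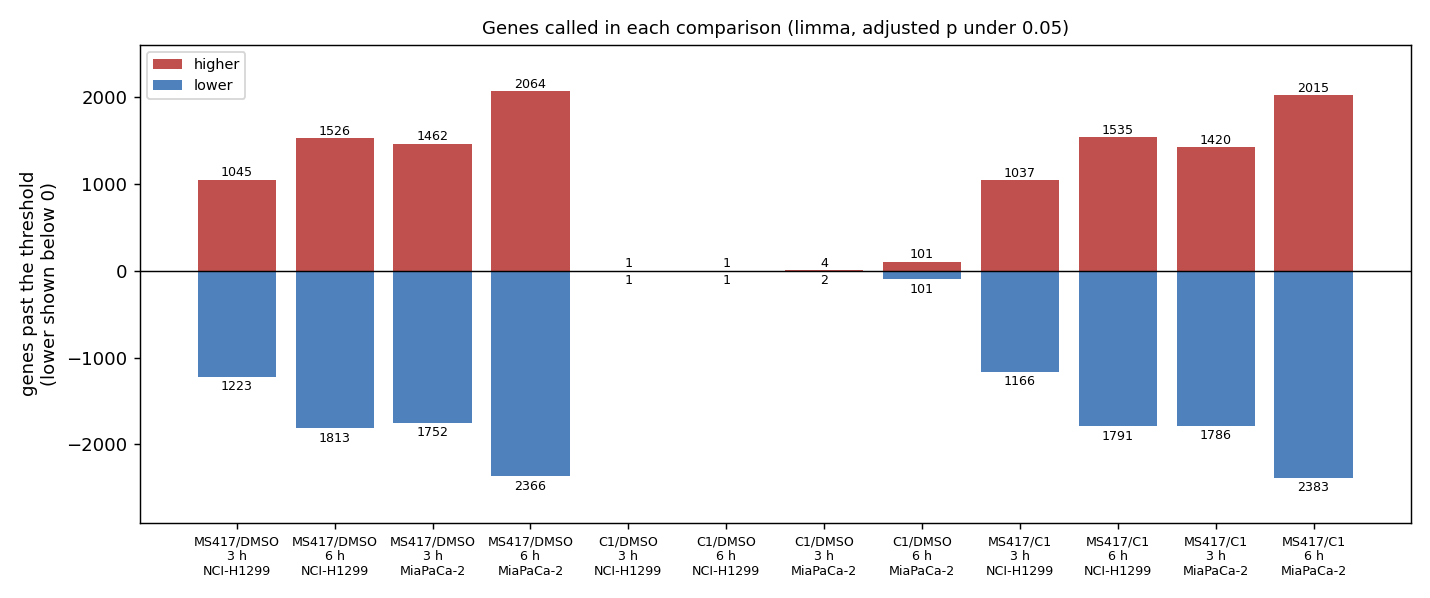
Genes called (y axis, number of genes; lower ones drawn below 0) in the 12 comparisons of a pair of groups (x axis) by limma at an adjusted p under 0.05. MS417 comparisons have between 2203 and 4430 genes and C1 comparisons with DMSO have 2, 2, 6 and 202.

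The comparison of C1 with DMSO asks what 10 µM of the inactive compound does. In NCI-H1299 limma called PPM1E (0.32 ± 0.056) and AHR, the aryl hydrocarbon receptor gene (−0.46 ± 0.081), at 3 h, and SSR3 (0.62 ± 0.112) and PPL (at least 1.12-fold lower) at 6 h. In MiaPaCa-2 at 3 h it called 6 genes: PKNOX2 (0.62), DYNC1LI1 (0.48), DLG4 (0.44), ADGRL3 (0.34), ATG13 (−0.34) and TFDP2 (−0.33, or 0.011 without scaling, against an unscaled median of all genes of 0.30). The other probe sets of PKNOX2, ADGRL3, ATG13 and TFDP2 were not called. At 6 h in MiaPaCa-2 it called 202 genes, 101 higher and 101 lower, with a median absolute change of 0.37. These named among the 202 were TMEM143 (at least 2.85-fold higher), ZXDC (0.87), NHLRC2 (0.83), SNCG (0.82) and PRRC1 (0.77), and the mevalonate kinase gene MVK (−1.75), GUSBP14 (−1.31), HLA-F-AS1 (−0.96), SIGLEC1 (−0.84) and ZNF576 (−0.83). The other probe sets of MVK (−0.61 and −0.21), GUSBP14 (−0.006) and ZNF576 (−0.11) were not called. None of the 10 genes named in advance was called in a C1 comparison with DMSO by limma. HEXIM1 read 0.19, −0.18, −0.28 and −0.25 with 95% intervals of −0.08 to 0.46, −0.45 to 0.09, −0.55 to −0.00 and −0.53 to 0.02. CDKN1A at 6 h in MiaPaCa-2 read 0.36 ± 0.117 (limma adjusted p = 0.0992). At an unadjusted p under 0.05 limma gave 372, 658, 641 and 1325 genes, or 4.31%, 7.62%, 7.42% and 15.3% of those tested. camera called 0 of the 22 lists in each C1 comparison.

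The C1 counts move with single arrays. For C1 at 6 h in MiaPaCa-2, 202 became 120, 107 and 100 without C1 replicate 1, 2 or 3 and 109 without DMSO replicate 1, 110 with the arrays of that line alone, 49 with the compared groups alone and 2 without scaling. For C1 at 3 h in MiaPaCa-2, 6 became 11 and 33 without C1 replicate 1 or 3, and 11 and 21 without DMSO replicate 1 or 2. In NCI-H1299, leaving out single arrays gave 1, 8 and 1 (C1 replicates 1 to 3) and 4, 5 and 5 (DMSO replicates 1 to 3) genes at 3 h, and 17, 10 and 8 (C1) and 21, 0 and 5 (DMSO) at 6 h. The DMSO arrays of MiaPaCa-2 at 6 h also differed from those at 3 h by 179 called genes, against 5 between the C1 arrays of the same times.

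MS417 was set against C1 at the same times to compare the inhibitor with the inactive compound, at 0.5 µM and 10 µM. limma called 2203 genes at 3 h and 3326 at 6 h in NCI-H1299, and 3206 and 4398 in MiaPaCa-2, with 1166, 1791, 1786 and 2383 of them lower under MS417. Without scaling the counts were 404, 1302, 1357 and 1881, with 294, 1165, 1140 and 1251 lower. With median or 75th percentile scaling more genes were higher than lower in all 4. In the order used above, HEXIM1 differed by 1.63 ± 0.133, 2.01 ± 0.133, 0.68 ± 0.133 and 0.65 ± 0.133 (its other probe set 3.02, 3.34, 1.73 and 1.26), and CDKN1A by 1.68, 2.00, 1.63 and 1.64 with an SE of 0.117. SERPINI1 was 2.29-fold and 3.33-fold higher (SE 0.078 on the log2 scale) in NCI-H1299 and was at least 3.80-fold and at least 6.93-fold higher in MiaPaCa-2. H2BC21 differed by 2.22, 2.62, 1.91 and 2.39 (SE 0.138) and BRD2 was 1.77-fold, 2.13-fold, 2.63-fold and 2.83-fold higher (SE 0.068 on the log2 scale). MYC differed by −0.46, −0.41, −0.48 and 0.24 (SE 0.051). FOSL1 was lower than under C1 in NCI-H1299 (2.42-fold and 2.83-fold) and at 3 h in MiaPaCa-2 (−0.56), and read −0.07 (95% interval −0.25 to 0.11, limma adjusted p = 0.586) at 6 h. BRD3 was higher by 0.35 (its other probe set 0.13, not called), 0.39 and 0.25 in the other comparisons (the last 0.21 and no longer called without C1 6 h replicate 1) but read 0.11 (limma adjusted p = 0.332) at 3 h in MiaPaCa-2. CDK9 was higher at 6 h (0.82 and 0.47) and read 0.14 and 0.05 at 3 h (limma adjusted p = 0.549 and 0.905). CCND1 was lower at 6 h (−0.54 and −0.45, the latter −0.24 and no longer called without C1 replicate 3) and read 0.07 and −0.13 at 3 h (limma adjusted p = 0.852 and 0.526). The histone, MYC and ribosome biogenesis, G2/M, and CDK inhibitor lists were called by camera against C1 in all 4 comparisons. Called against DMSO but not against C1 were ATF4 and the unfolded protein response (camera adjusted p = 0.0866) and hypoxia (adjusted p = 0.189) at 3 h and NRF2 (adjusted p = 0.117) at 6 h in NCI-H1299. In MiaPaCa-2 the NF-kB list was another at 3 h (camera adjusted p = 0.0702). Called by camera against C1 alone were, in MiaPaCa-2, cholesterol at 3 h (adjusted p = 0.0445) and heat shock (adjusted p = 0.0384) and aryl hydrocarbon receptor targets (adjusted p = 0.039) at 6 h. The last 2 calls are lost with an estimated correlation (camera adjusted p = 0.0741 and 0.0675 with an estimated correlation).

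The changes under MS417 and under C1, each against DMSO, correlated across genes at r = 0.22, 0.17, 0.13 and 0.16 (Spearman 0.21, 0.18, 0.14 and 0.16), and genes are not independent replicates. Both share the 3 DMSO arrays, which alone gives 0.50 in each simulation without any effect, and the DMSO arrays are too few to split. The covariance exceeded the simulated one by 0.000276, 0.00107, 0.000156 and 0.00764, the last at 6 h in MiaPaCa-2. Among the upper 60% of genes by mean level the values were −0.000217, 0.000355, −0.000342 and 0.00669, so at 3 h the sign turned in both lines.

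The difference of the MS417 change between the lines asks whether the pancreatic and the lung cells respond alike. HEXIM1 rose less in MiaPaCa-2, by −1.42 ± 0.188 at 3 h and −1.44 ± 0.188 at 6 h, and its other probe set gave −1.10 and −1.33. Histone genes rose more in NCI-H1299, with a median difference of −0.08 at 3 h (9 of 27 genes lower in MiaPaCa-2, 0 higher, camera adjusted p = 0.039, adjusted p = 0.0946 with an estimated correlation) and −0.43 at 6 h (12 lower, 0 higher, camera adjusted p = 2.23e-05, adjusted p = 0.0023 with an estimated correlation). Part of this may reflect signal near the floor: H2AC8, H2BC11 and H2AC16 rose at 6 h in NCI-H1299 (1.22, 1.57 and 0.85) but read 0 in MiaPaCa-2. Histone probe sets over log2 6 had 6 h medians of 1.67 in NCI-H1299 and 1.10 in MiaPaCa-2 (unique), and 2.65 and 2.34 (shared). Immediate early genes rose more in MiaPaCa-2, with a median difference of 0.21 at 3 h (12 higher, 6 lower, camera adjusted p = 0.0138, adjusted p = 0.0727 with an estimated correlation) and 0.45 at 6 h (21 higher, 2 lower, camera adjusted p = 3.54e-08, adjusted p = 0.000424 with an estimated correlation). Ribosome biogenesis genes fell further in MiaPaCa-2 at 3 h (median difference −0.12, 9 of 43 lower, 1 higher, camera adjusted p = 0.0337, adjusted p = 0.0727 with an estimated correlation). Adjusted over the list alone, the histone counts were 9 lower and 1 higher, then 13 lower, the immediate early counts 12 and 7, then 22 and 2, and the ribosome biogenesis counts 10 lower and 1 higher. limma called 1539 genes at 3 h, 699 of them higher in MiaPaCa-2, and 2925 at 6 h, 1450 of them higher (127, 78 higher, and 1712, 1591 higher, without scaling, and 1300, 759 higher, and 3184, 2456 higher, with median scaling). JAG1, a Notch ligand gene, rose in NCI-H1299 (1.21 and 1.04) and fell in MiaPaCa-2 (−1.09 and −1.44), and PTX3 at 6 h fell in NCI-H1299 (−2.03) and rose in MiaPaCa-2 (1.09). MYC differed by 0.72 ± 0.072 at 6 h and by 0.02 (95% interval −0.13 to 0.17, limma adjusted p = 0.907) at 3 h. CDKN1A differed by 0.09 (−0.25 to 0.43, limma adjusted p = 0.804) and 0.14 (−0.20 to 0.48, limma adjusted p = 0.56), and H2BC21 by −0.21 (−0.61 to 0.19, limma adjusted p = 0.536) and −0.39 (−0.80 to 0.01, limma adjusted p = 0.128). CDK9 (−0.28 and 0.02, limma adjusted p = 0.371 and 0.966) and BRD3 (−0.12 and −0.02, limma adjusted p = 0.566 and 0.957) were not called. At 3 h and 6 h BRD2 (0.70 and 0.37), SERPINI1 (0.69 and 1.08) and FOSL1 (0.81 and 1.54) were higher in MiaPaCa-2 relative to NCI-H1299, the SERPINI1 values as lower bounds because its DMSO arrays lay at the floor in MiaPaCa-2. CCND1 read −0.42 at 3 h (limma adjusted p = 0.151) and −0.54 at 6 h (limma adjusted p = 0.034), where its other probe set gave −0.07 and the call ended with median scaling (−0.35) and the difference was 0.005 without scaling. The unscaled median of all genes in the line difference at 6 h was 0.44. With C1 in place of DMSO, CCND1 at 6 h read −0.54 in NCI-H1299 and −0.45 in MiaPaCa-2 (its other probe set −0.54 and −0.65). Across all genes the changes in the lines correlated at r = 0.63 at 3 h and 0.61 at 6 h, and 1208 genes fell in both at 6 h (497 for independent lists), 940 rose in both (365) and 165 were called in opposite directions (851).

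**Figure D4:**
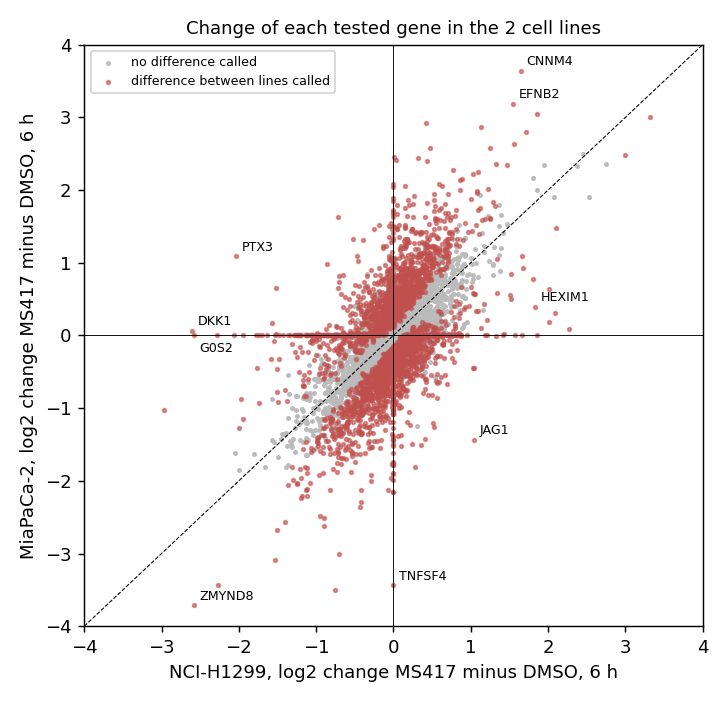
Log2 change of each of 8639 genes at 6 h, MS417 minus DMSO, in NCI-H1299 (x axis) and MiaPaCa-2 (y axis), with red points for the 2925 genes whose change differed between the lines by limma and a dashed line for equal change. HEXIM1 lies right of the dashed line, JAG1 (1.04 and −1.44) and PTX3 (−2.03 and 1.09) in opposite quadrants, and genes at the floor in a line lie on an axis.

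The difference between 6 h and 3 h, each against the DMSO of its time, asks how the response developed. In NCI-H1299 histone genes rose further (median 0.42, 12 of 27 higher, 0 lower, camera adjusted p = 2.1e-12, and 14 higher adjusted over the list alone). BRD2 and SERPINI1 rose further there by 0.43 ± 0.096 and 0.48 ± 0.11 (−0.18 and −0.10 without scaling). The unscaled median of all genes in this time difference was −0.58, and both genes lay above it. In MiaPaCa-2 immediate early genes were higher at 6 h than at 3 h (median 0.18, 14 of 34 higher, 4 lower, camera adjusted p = 0.0328; 17 and 7 adjusted over the list alone), a call that is lost with an estimated correlation (adjusted p = 0.215 with an estimated correlation). MYC in MiaPaCa-2 turned from lower to higher, a difference of 0.74 ± 0.072, and stood at 0.04 (95% interval −0.10 to 0.19, limma adjusted p = 0.815) in NCI-H1299. CDK9 (0.61 ± 0.192) and FOSL1 (0.51 ± 0.126) were higher at 6 h than at 3 h in MiaPaCa-2. The CDK9 call ended without MS417 3 h replicate 2 (0.47), DMSO 3 h replicate 1 (0.53) or DMSO 6 h replicate 3 (0.54). HEXIM1 did not pass in NCI-H1299 (0.01, 95% interval −0.37 to 0.40) or in MiaPaCa-2 (−0.01, −0.40 to 0.38), limma adjusted p = 1.0 in both. CDKN1A (0.21 and 0.26, limma adjusted p = 0.512 and 0.292), H2BC21 (0.54 and 0.36, limma adjusted p = 0.0741 and 0.207), CCND1 (−0.31 and −0.42, limma adjusted p = 0.374 and 0.124) and BRD3 (0.17 and 0.27, limma adjusted p = 0.424 and 0.0919) did not pass. CDK9 (0.30, limma adjusted p = 0.373) and FOSL1 (−0.22, limma adjusted p = 0.305) were not called in NCI-H1299, nor was BRD2 (0.10, limma adjusted p = 0.563) in MiaPaCa-2. SERPINI1 lay at the floor on the DMSO arrays of both times in MiaPaCa-2, so the size of its time difference there is not known. limma called 1044 genes in NCI-H1299 and 2053 in MiaPaCa-2, 448 and 1035 of them higher at 6 h (1651, 5 higher, and 89, 18 higher, without scaling, and 686 in NCI-H1299 with the compared groups alone). The DMSO arrays of 6 h and 3 h, which enter these differences, differed by 18 called genes in NCI-H1299 and 179 in MiaPaCa-2. The C1 arrays of the same times differed by 10 and 5. Across genes the 3 h and 6 h changes correlated at r = 0.73 in NCI-H1299 and 0.78 in MiaPaCa-2, and 47 and 103 genes were called in opposite directions (435 and 819 for independent lists).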

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

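The tests of the DMSO arrays, of the C1 movement, of the arrays that lower the C1 count alike and of the S phase share were chosen only after the result was seen, as was the look at bright histone probe sets. The 75th percentile scaling was also added after the data had been seen, and the other tests in this part were set beforehand.

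The differences between the cell lines in the MS417 change are listed here because the test of the difference passed. At 3 h 1539 genes differed, MiaPaCa-2 minus NCI-H1299: HEXIM1 −1.42, BRD2 0.70, SERPINI1 0.69, FOSL1 0.81, DYRK3 2.29, UGCG 2.11, TUFT1 2.07, DUSP5 2.03, LMO4 2.01, GAS1 −2.47, JAG1 −2.30, RUNX1-IT1 −1.95, BEGAIN −1.81 and FJX1 −1.78. The other probe sets of LMO4 (0.226) and GAS1 (−0.372) were not called. At 6 h 2925 genes differed: HEXIM1 −1.44, MYC 0.72, BRD2 0.37, SERPINI1 1.08, FOSL1 1.54, CCND1 −0.54, PTX3 3.12, DKK1 2.67, G0S2 2.58, CSRP2 2.498, FARP2 2.44, TNFSF4 −3.43, PDE10A −2.74, JAG1 −2.48, RIN2 −2.31 and DHRS2 −2.19. All MS417 and DMSO arrays of 1 line lay at the floor for GAS1 and BEGAIN at 3 h and TNFSF4 at 6 h (NCI-H1299) and for G0S2 at 6 h (MiaPaCa-2), so these values carry the change of the other line alone. SERPINI1, RUNX1-IT1, FARP2, PDE10A, RIN2 and DHRS2 had at least 1 group at the floor, so their differences are not exact. The CCND1 difference at 6 h ended with median scaling (−0.35), with the mean of its probe sets (−0.30) and without NCI-H1299 MS417 replicate 1 (−0.53) or 2 (−0.44), NCI-H1299 DMSO replicate 2 (−0.52) or 3 (−0.54), MiaPaCa-2 MS417 replicate 2 (−0.53) or 3 (−0.52) or MiaPaCa-2 DMSO replicate 3 (−0.46). Of the gene lists, histones (−0.079), MYC and ribosome biogenesis (−0.12) and immediate early genes (0.21) differed in their median at 3 h, calls that are lost with an estimated correlation (camera adjusted p = 0.0946, 0.0727 and 0.0727 with an estimated correlation), and histones (−0.43) and immediate early genes (0.45) at 6 h. The histone list holds H2AC8, H2BC11 and H2AC16, whose changes read 0 in MiaPaCa-2.

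The differences between 6 h and 3 h passed the same kind of test. In NCI-H1299 1044 genes differed: BRD2 0.43, SERPINI1 0.48, ZNF528 1.60, CD4 1.52, TRAF6 1.42, H2BC11 1.25, GNA13 1.16, NAV3 −1.88, SLC19A1 −1.65, CHAC1 −1.60, G0S2 −1.51 and DCLRE1A −1.45, and the histone median differed by 0.42. TRAF6, H2BC11 and SLC19A1 had at least 1 group at the floor, and 2 of the other probe sets of SLC19A1 were not called. In MiaPaCa-2 2053 genes differed: MYC 0.74, CDK9 0.61, SERPINI1 0.87, FOSL1 0.51, CXCL2 1.60, SNAPC4 1.59, ITFG2 1.43, ZNF143 1.42, URB2 1.38, HDAC9 −2.24, ZMYND8 −2.11, PSD3 −2.03, PDE10A −2.01 and DENND1B −1.91, and the immediate early median differed by 0.18, a call that is lost with an estimated correlation (camera adjusted p = 0.215 with an estimated correlation). SERPINI1 and PDE10A had at least 1 group at the floor, so their differences are not exact, and SNAPC4, ITFG2, ZMYND8 and PDE10A had another probe set that was not called. Probe sets with several symbols or none, which no comparison used, also carried signal: of 1830 above the floor, 353, 574, 574 and 780 were called in the 4 MS417 comparisons with DMSO and 0, 2, 2 and 67 in those of C1.

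Other splits of the same arrays were tried for each count. For each comparison of MS417 with DMSO or with C1, 1 of 10 splits, the real one, reached the count, and the highest other counts were 9, 13, 9 and 13 against DMSO and 13, 22, 6 and 5 against C1. For C1 against DMSO 7, 8, 4 and 1 of 10 splits reached 2, 2, 6 and 202 genes. With 10 splits no share can fall under 0.05, so these comparisons do not exclude chance. For the differences between lines and times 1 of 100 splits, the real one, reached the count (highest others 389, 1253, 163 and 763). For the genes called the same way in all 4 comparisons 1 of 100 did (highest other 0). Groups mixed in the other splits carry the change under test as spread, which lowers their counts. These 5 counts therefore do not exclude chance either.

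C1 called 202 genes at 6 h in MiaPaCa-2 and at most 6 elsewhere, and the DMSO arrays of that time differed from those of 3 h by 179 genes, against 5 between the C1 arrays, which is consistent with DMSO arrays of 6 h that stand apart. The called genes moved further between the times in DMSO than in C1 (median difference −0.142, 153 of 202 genes, and in the mean per array −0.150 with a 95% interval of −0.277 to −0.023 from the spread of the 3 h arrays), which argues against C1 as the only source. The median movement was 0.109 in C1 against 0.252 in DMSO, and 62 of the 202 were called between the DMSO times, so a movement by C1 in part stays open. The lowest count with 1 array left out was 100 and the highest 187, short of the bound set beforehand (every count above 100), but 4 of the 6 arrays lowered it alike (100, 107, 109 and 120), which argues against 1 array that decides the calls. A biological effect of C1 that offsets a change over time in DMSO was not tested apart from this.

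Histone genes rose together under MS417. Of 17 probe sets marked as unique, 23.5% were called higher at 6 h in both lines, against 81.8% of 11 shared ones (47.1% and 86.4% of the tests in single lines), so cross-hybridisation between histone genes stays open, although all unique probe sets over log2 6 (3 of 3 in each line) rose. The median of the G1/S genes was −0.092 in NCI-H1299 (95% interval −0.221 to −0.021) and −0.128 in MiaPaCa-2 (−0.252 to 0.025), or −0.0972 and 0.0053 with median scaling. These intervals come from resampling the 38 genes and leave out the spread between arrays. Members of the G1/S list went both ways (8 and 11 of 38 higher, 13 and 18 lower), so a larger share of cells in S phase stays open. Of 10 tests of replication-independent histone genes (5 genes in 2 lines) 60% were called higher and 0 lower, above the bound set beforehand. Of all 8639 genes 1526 and 2064 rose at 6 h. H1-10 (0.76 and 0.96) and H2AZ2 (0.26 and 0.24) rose in NCI-H1299 and MiaPaCa-2. H2AZ1 (0.19) and H3-3A (0.55) rose in MiaPaCa-2 only. MACROH2A1 read −0.04 and −0.06 and was not called, so a rise of every kind of histone gene is not shown.

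The MS417 changes differed between the lines. Of the 2925 genes that differed at 6 h, 14.3% lay at the floor in 1 line, which argues against genes measured in 1 line as the cause. With 75th percentile scaling 84.5% differed in the same direction and with median scaling 73.8%, which argues against the scaling between the lines as the whole cause, but without scaling 1381 of the 2925 were also called and median scaling gave 2456 higher and 728 lower genes (1450 and 1475 before), so the balance of directions stays open. Opposite signs were seen for 907 of them (31.01%), counting changes that were not called, but 165 genes were called in opposite directions, JAG1 and PTX3 among them, which argues against a uniform difference in the size of the response. A property of the cell lines remains and was not tested, since each line stands for 1 cancer.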

How the results depend on the processing

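Of 559 results for named genes 380 kept their direction and their side of the threshold under every setting run for them, 172 lost the call at least once and 17 turned at least once. Leaving out dim genes covered part of these results, and all probe sets and the 2-fold change gave counts alone. Of 39 results for gene lists 24 kept both under unscaled values, median and 75th percentile scaling, the block and the estimated correlation, 15 lost the call at least once and 0 turned. For lists the direction is that of camera, relative to all other genes, so it can hold where an unscaled median changes sign. The unscaled values account for 155 of 483 lost calls and 13 of 20 turned values of named genes, and for 10 of 19 lost calls of lists. Changes in genes near the floor are limited by signal over background.

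Without scaling, MS417 against DMSO called 309 genes at 3 h and 3988 (3893 lower) at 6 h in NCI-H1299 and 885 and 1781 at 3 h and 6 h in MiaPaCa-2, C1 called 1 and 4 in NCI-H1299 and 2 at 6 h in MiaPaCa-2, and MS417 against C1 called 404, 1302, 1357 and 1881. The differences between lines then had 127 and 1712 genes, those between times 1651 and 89, and 122 genes were called alike in all 4 comparisons. The unscaled array levels shift whole comparisons, with a median of all genes of −0.45 for MS417 at 6 h in NCI-H1299, −0.58 for its time difference, 0.44 for the line difference at 6 h, 0.14, −0.28 and 0.30 for C1 at 3 h and 6 h in NCI-H1299 and 3 h in MiaPaCa-2, and −0.15 and −0.13 for MS417 against C1 at 6 h in NCI-H1299 and 3 h in MiaPaCa-2. Unscaled values turned BRD3 (−0.18), BAG3 (−0.28), NQO1 (−0.25), ACTA2 (−0.028), ALAS1 (−0.19), GUSB (−0.33) and B2M (−0.29) at 6 h in NCI-H1299, BRD2 (−0.18) and SERPINI1 (−0.10) in its time difference, CCND1 (0.005) in the line difference at 6 h, and BST2 (0.029), SOX9 (0.03) and, for C1, TFDP2 (0.011) at 3 h in MiaPaCa-2.

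Median scaling gave C1 0 and 6 genes in NCI-H1299 and turned KRT18 at 6 h there (0.007) and COL1A2 (0.077) and HPRT1 (0.15) at 6 h in MiaPaCa-2. Under it the share of lower genes was 40.7% and 35.1% for MS417 in MiaPaCa-2 (54.5% and 53.4% before), 27.0% for C1 at 6 h there (50% before), 43.8% and 39.6% for MS417 against C1 there, 41.6% and 22.9% for the line differences and 68.0% and 32.2% for the time differences, and the median of all genes in the line difference at 6 h was 0.12. Scaling by the 75th percentile gave C1 4 genes at 6 h in NCI-H1299, turned KRT18 (0.074) and HPRT1 (0.027) and gave 43.5% lower genes at 3 h in NCI-H1299 (53.9% before). The mean of all probe sets turned MUC1 at 6 h in MiaPaCa-2 (−0.007), whose probe sets read 0.44 and −0.47, and the DMSO arrays of 3 h as control turned HPRT1 (0.044) and gave C1 47 genes at 6 h in MiaPaCa-2. Except for the probe sets of MUC1, the cause was not tested.

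For C1, a floor of 16 gave 5 genes at 3 h in NCI-H1299 and 3 at 3 h in MiaPaCa-2, leaving out dim genes 0, 0 and 3 at 3 h and 6 h in NCI-H1299 and 3 h in MiaPaCa-2, the filter for a whole group 0 at 6 h in NCI-H1299, the mean of probe sets 3 at 3 h in MiaPaCa-2, the trended robust prior 0 and 0 in NCI-H1299, and all probe sets 9, 0, 11 and 312. The arrays of the line alone gave C1 0 and 0 in NCI-H1299 and 110 at 6 h in MiaPaCa-2. The compared groups alone gave C1 0, 0, 0 and 49, and the time difference in NCI-H1299 686, with fewer arrays behind the variance. A change of at least 2-fold left 128, 267, 371 and 700 genes for MS417 against DMSO, 0, 0, 0 and 3 for C1, 138, 271, 361 and 690 for MS417 against C1, 143 and 331 for the line differences, 45 and 138 for the time differences and 44 in all 4.

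With single arrays left out the counts ran from 1911 to 2178, 2995 to 3166, 2925 to 3026 and 4165 to 4231 for MS417 against DMSO, 1 to 8, 0 to 21, 9 to 33 and 100 to 187 for C1, 1831 to 2097, 2977 to 3206, 2885 to 3056 and 4067 to 4155 for MS417 against C1, 1359 to 1441 and 2663 to 2828 for the line differences, 842 to 1003 and 1846 to 1992 for the time differences, and 900 to 1008 for all 4. The replicate number as a block gave C1 1 gene at 6 h in NCI-H1299, ended 5 of 559 calls of named genes and moved no other count by over 1.5 times. Arrays of 1 number correlated at −0.42 to 0.28 over 90 pairs (median −0.0047, 11 over 0.1), so the number does not pair samples. No source names the authors' test, so it was not run.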

Other observations

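The test of zinc finger genes in this part was chosen only after the result was seen, and that of neighbouring genes was set beforehand. Some genes turned between the times or the lines. In MiaPaCa-2 the pluripotency gene NANOG rose by 0.90 ± 0.113 at 3 h and fell by at least 0.79 at 6 h, and BHLHE40, a repressor in the circadian clock, fell by 0.53 ± 0.14 and then rose by 0.57 ± 0.14. In NCI-H1299 TRAF6, a signalling adaptor gene, fell by at least 0.80 and then rose by 0.61 ± 0.215. UGCG, a glycolipid synthesis gene, fell at 3 h in NCI-H1299 (−0.65 ± 0.051) and rose in MiaPaCa-2 (1.46 ± 0.051). These genes were chosen after their values were seen.

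As a hypothesis, genes named ZNF, mostly zinc finger transcription factors, fall under MS417. The medians of 202 such genes were −0.179 and −0.052 at 3 h and 6 h in NCI-H1299 and −0.151 and −0.005 in MiaPaCa-2, with 0%, 0%, 0% and 1.48% of 10000 random lists of like level at or below them, and 71, 60, 75 and 63 of them fell while 6, 43, 21 and 36 rose. The value at 6 h in MiaPaCa-2 is close to 0, was 0 with median scaling and −0.041 with 75th percentile scaling (which gave −0.018 at 6 h in NCI-H1299), and C1 in MiaPaCa-2 gave −0.003 with 0% of random lists at or below it, so −0.005 carries no weight. The random lists leave out the spread between arrays, so the 0% values under MS417 do not measure significance either. Of all 8639 genes, 1526 rose and 1813 fell at 6 h in NCI-H1299.

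As a further hypothesis, genes that neighbour each other change alike. Over 8235 pairs the changes correlated at 0.0227, −0.000678, 0.0271 and 0.0192 under MS417 (permutation adjusted p = 0.11, 0.56, 0.097 and 0.11 over 8 tests of 10000 shuffles), and 0 of these passed.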
